A study of Mus musculus with 16 samples.

How the data were processed

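RNA of mouse esophagus was measured by CEL-Seq, a protocol that sequences short tags from the 3' ends of transcripts, on a NextSeq550 instrument, per the labels' protocols. The 16 libraries formed 4 groups of 4 by genotype (WT or Il13ra1 knockout, KO) and treatment (OXA or vehicle). The labels gave no batch, sex or pairing. The letter-and-digit codes in the titles were read here as animal codes. They differed between the groups and paired no libraries.

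Per the submitters' processing notes, the authors checked reads with FastQC 0.11.5, trimmed them with Trim Galore and cutadapt 1.10, aligned them with TopHat2 2.1.0 and Bowtie2 2.2.6 to GRCm38, counted them per gene with HTSeq 0.6.1 and normalized them with DESeq2 1.28.0. The annotation release and the handling of molecular identifiers were not given in the sources used here. The deposited values were a signal that is never negative, gene counts divided by 1 size factor per library. Within each library the values were whole multiples of 1 step: with a tolerance of 0.1 of a read, 100% of values came out as whole reads in every library. Reads were recovered on that basis and gave the depth of each library. There were 41411 genes, of which 14402 were at 0 in every library. By identifier 41383 were found in GENCODE M21, and 40518 of these (97.9%) had identical coordinates. There were 78 symbols shared by more than 1 gene identifier. No entry lacked a gene.

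The main test was limma 3.58.1 in R 4.3.3 on log2(value + 1), with a mean for each of the 4 groups over all 16 libraries, 1 shared spread per gene and eBayes with a trend. It was two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05, and all adjusted p-values for genes came from it unless another tool is named. Tested genes had a value of at least 5 in at least 4 libraries (16748 genes). Fold changes are on the log2(value + 1) scale, which understates the change of low genes. The 5 comparisons were OXA against vehicle in WT, the same in KO, the interaction (KO effect minus WT effect), KO against WT under vehicle and KO against WT under OXA. The WT and KO effects shared no library. Group values are means ± SD of the deposited values (n = 4), and fold changes are given ± SE.

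The comparisons, the tests, 26 gene lists and the rule for naming genes were fixed before the data were examined. The lists were eosinophil markers, IL-4 and IL-13 response genes, type 2 cytokines and alarmins, IL-4 and IL-13 receptor components, T cell markers, B and plasma cell markers, mast cell and basophil markers, neutrophil markers, macrophage and dendritic cell markers, basal epithelial markers, suprabasal differentiation genes, hyperproliferative and alarmin keratinocyte genes, cell cycle genes, fibroblast and matrix genes, endothelial markers, smooth muscle markers, skeletal muscle markers, adipocyte markers, interferon response genes, inflammatory chemokines and cytokines, thyroid markers, glandular stomach markers, airway markers, immediate early and stress genes, mitochondrially encoded genes and sex-linked genes. Each list was tested with limma's camera at a preset correlation of 0.01, two-sided, adjusted over the 26 lists of a comparison, and again with an estimated correlation and with fry. Camera compares a list with all other tested genes, while fry tests whether a list's genes move, on balance, one way. A score per library, the mean log2(value + 1) of the tested members, was compared by an exact permutation test over 70 assignments, two-sided, whose smallest possible p is 0.0286.

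Genes were named by 3 parts of the rule. In each comparison it took the 10 genes with the largest and the 8 with the smallest fold change among those that passed, had no overlap between the groups and had a mean of at least 10 in the higher group (for the interaction the 8 most negative and 6 most positive), passing over unnamed and predicted genes. It also took up to 4 tested members of each list with the smallest p, and always the receptor chains, type 2 cytokines and a few keratin, chemokine and tissue genes, whatever their values. Genes named outside the rule are said to have been chosen after their values were seen.

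Alternatives were pseudocounts of 0.5 and 5, no filter beyond a value above 0 in at least 1 library (27009 genes), a stricter filter of 20 (13871 genes), equal library totals, quantile normalization, a fit to only the groups compared, no trend, a robust fit, array weights, and each library left out in turn. On the recovered reads, edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0 (Wald) were run. Thinning every library to 5.61 M reads was chosen after seeing the data. Other splits of the libraries into groups of the same sizes were refitted to count how often they called as many genes. The procedure was tested on simulated data with known changes: of 100 genes changed 2-fold and 100 changed 4-fold in the WT libraries it called 48 and 85, with 8 unchanged genes called out of 16431 genes. The changed genes were drawn from those with a mean of at least 20, and the scaling between libraries was known. Far fewer genes were changed than were called in WT. Lower genes and errors of scaling were thus not covered. Plots and summaries used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and tables were read with data.table version 1.17.8.

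Precision was set by depth, which ran from 5.61 M to 27.3 M (mega) recovered reads per library, and by 4 libraries per group. Where a group had no read, the limit given is 3 reads over the group's total. Such limits cover counting error only. The bootstrap interval of the X to autosome ratio came from resampling genes within 1 library. Genes under the filter were not tested in the main comparisons and are reported as reads. No library was left out. Not every gene called between genotypes is named, and 1 result among them is not reported here. Raw reads were not used here.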

Results

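The series measured gene expression in the esophagus of C57BL/6 mice in a model of eosinophilic esophagitis, an allergic disease in which eosinophils enter the esophageal lining. Mice received OXA, an oxazolone hapten that sensitizes the skin and provokes contact allergy, or vehicle. They were wild type (WT) or lacked Il13ra1 (KO), the chain that pairs with Il4ra to form the type II IL-4 receptor for IL-13. Each of the 4 groups held 4 libraries. Depth, as reads recovered from the deposited values, was 7.64 ± 1.70 M (SD, n = 4) in WT vehicle, 23.3 ± 3.63 M in WT OXA, 12.9 ± 3.64 M in KO vehicle and 11.6 ± 2.71 M in KO OXA (M, mega). Depth therefore moved with the groups, and WT OXA was deepest. The share of mitochondrial rRNA moved too: it was 1.34% ± 0.27 in WT vehicle, 0.453% ± 0.0063 in WT OXA, 1.14% ± 0.431 in KO vehicle and 0.776% ± 0.273 in KO OXA. Whether these differences came from the handling of the libraries was not tested. Beyond the title codes, read here as animal codes, the labels do not say how separate the samples were. The p-values therefore measure only the spread between these samples.

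**Figure D1:**
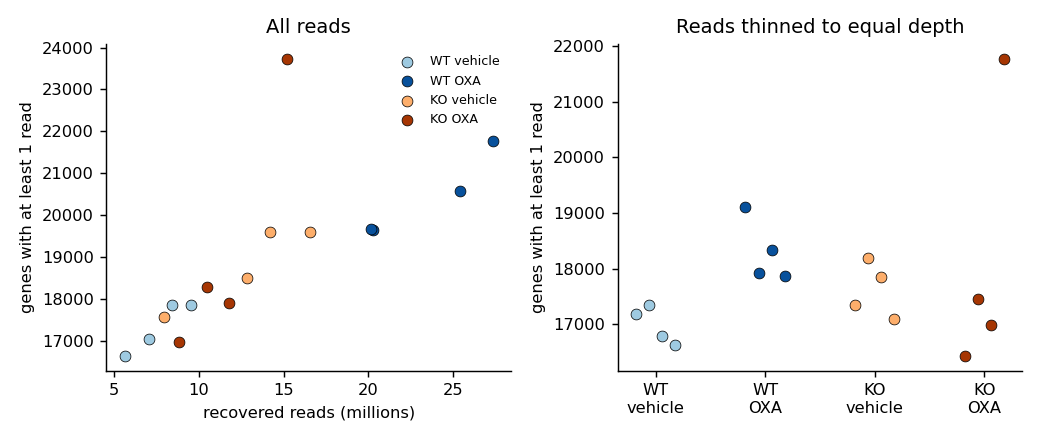
Left, recovered reads per library (M) against the number of genes with at least 1 read; right, genes with at least 1 read per library after thinning every library to 5.61 M reads, by group. KO OXA replicate 4 detected 21771 genes at equal depth, above the 19105 of the next library.

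Il13ra1 (ENSMUSG00000017057, GRCm38 chromosome X, 36112110 to 36171259) was read in every sample. Its values in WT vehicle were 207, 226, 197 and 134, and in WT OXA 584, 673, 752 and 874. In KO vehicle they were 31.2, 64.7, 48.7 and 55.8, and in KO OXA 44.0, 174, 68.1 and 110.3. The means were 191 ± 39.8, 721 ± 122.8, 50.1 ± 14.2 and 99.1 ± 56.9 (SD, n = 4). Il13ra1 was lower in KO than in WT under vehicle by a log2 fold change of -1.93 ± 0.32 (adjusted p = 0.0267) and under OXA by -3.02 ± 0.32 (adjusted p = 1.1e-06). The call under vehicle was lost without WT vehicle replicate 1, 2 or 3, WT OXA replicate 2, or KO vehicle replicate 1, 3 or 4 (adjusted p from 0.0529 to 0.121). It was also lost without a filter (0.0877), with equal library totals (0.0694) and without trend (0.128). Within KO, its log2 fold change under OXA stood at 0.84 ± 0.32 and did not pass (adjusted p = 0.237, but 0.0455 with DESeq2). A 3' tag may lie outside the deleted part of the gene, in which case its reads check nothing about the deletion.

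The first comparison asked what the OXA model does to the WT esophagus. Chil4, a chitinase-like protein induced by IL-13, was at 1397 ± 1148 under vehicle and at 178990 ± 66194 under OXA, a log2 fold change of 7.42 ± 0.72 (adjusted p = 2.98e-07). Krt6a, a keratin of wounded and hyperproliferative epithelium, was at 1016 ± 623 and then at 87445 ± 20053 (6.63 ± 0.46, adjusted p = 2.25e-09). Flg, filaggrin of the cornified layer, was at 219.6 ± 114 and then at 1.70 ± 1.24, a change of -6.38 ± 0.47 (adjusted p = 5.68e-09). In all 3 genes the 4 OXA libraries lay apart from the 4 vehicle libraries. Of 16748 genes tested, 3019 rose and 2673 fell (34%).

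**Figure D2:**
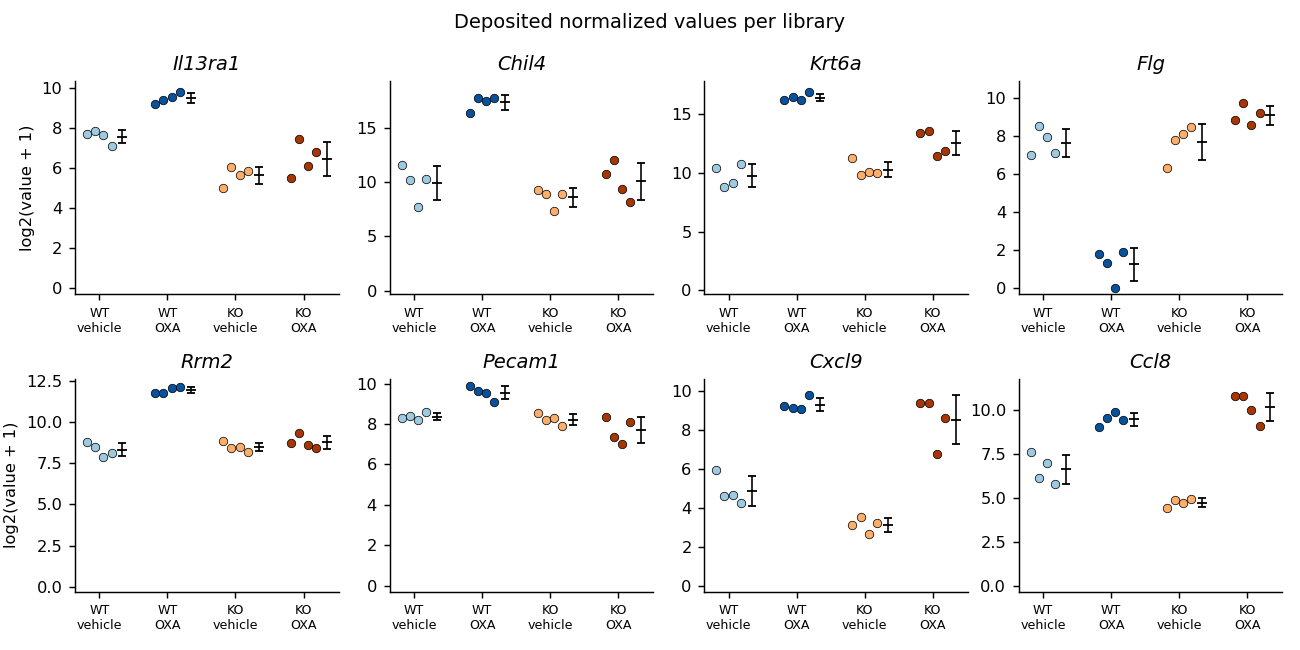
Deposited values as log2(value + 1) for 8 genes in each of the 16 libraries, by group; points are libraries and bars are means ± SD (n = 4). Chil4, Krt6a and Rrm2 were highest in WT OXA, and Flg was lowest there.

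Of 23 IL-4 and IL-13 response genes tested in WT, 15 rose and 2 fell (16 and 3 adjusted over the list alone; camera adjusted p = 4.7e-05, and adjusted p = 0.0791 with an estimated correlation). Alox15, a lipoxygenase, rose by 6.66 ± 1.0 (adjusted p = 5.03e-05), and Socs1, a feedback inhibitor of cytokine signalling, rose by 2.83 ± 0.31 (adjusted p = 1.23e-06). Ccl11 (eotaxin-1) rose by 1.27 ± 0.20 (adjusted p = 0.000101) and Retnla by 1.35 ± 0.25 (adjusted p = 0.000335), while Ccl24 stood at -0.46 ± 0.44 (adjusted p = 0.458). Of 8 receptor components 5 rose and 1 fell (5 and 1 over the list alone; adjusted p = 0.02095, and 0.1425 with an estimated correlation). Il4ra rose by 2.35 ± 0.24 (adjusted p = 5.17e-07), Il13ra2 by 3.64 ± 0.81 (adjusted p = 0.00187) and Il13ra1 by 1.92 ± 0.32 (adjusted p = 0.000152). Of 11 type 2 cytokines and alarmins 6 rose (7 over the list alone; adjusted p = 0.02095, and 0.1425 with an estimated correlation; 0.0659 with equal library totals). Il33, an epithelial alarmin, rose by 0.88 ± 0.21 (adjusted p = 0.00306), while Il5 stood at -0.52 ± 0.93 (adjusted p = 0.709) and Tslp at 0.83 ± 0.40 (adjusted p = 0.118, but 0.0288 with equal library totals).

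Genes of the epithelium both rose and fell in WT. Of 31 suprabasal differentiation genes 16 fell and 6 rose (17 and 7 adjusted over the list alone; adjusted p = 0.000248, and adjusted p = 0.3555 with an estimated correlation). Hrnr changed by -5.40 ± 0.41 (adjusted p = 8.85e-09), the protease Klk5 by -6.05 ± 0.52 (adjusted p = 5.4e-08) and Krt78 by -2.53 ± 0.21 (adjusted p = 3.04e-08). Krt13, the main suprabasal keratin of the esophagus, changed by -1.16 ± 0.42 (adjusted p = 0.0405), a call that was lost without a filter (0.321), with thinned reads (0.0609) and without 9 of the 16 libraries (every WT library but WT OXA replicate 4, and KO vehicle replicates 1 and 2; adjusted p from 0.0511 to 0.0998). Slurp2, a secreted keratinocyte protein, changed by -7.82 ± 0.47 (adjusted p = 3.83e-10), Aldh3a1 by -6.90 ± 0.24 (adjusted p = 4.17e-13) and Lce1k, a late cornified envelope gene, by -7.07 ± 0.37 (adjusted p = 6.29e-11). Of 20 hyperproliferative and alarmin keratinocyte genes 9 rose and 4 fell (9 and 5 over the list alone; adjusted p = 0.0757, but 0.0337 without WT vehicle replicate 2, 0.0299 without WT OXA replicate 3, 0.0403 with quantile normalization and 0.0429 with thinned reads). Krt16 rose by 8.12 ± 0.76 (adjusted p = 1.8e-07), and Sprr2h, a small proline-rich cornified envelope gene, by 7.41 ± 0.53 (adjusted p = 3.42e-09). Of 13 basal markers 2 rose and 6 fell (the same over the list alone; adjusted p = 0.0551, but from 0.0306 to 0.0443 without WT vehicle replicate 1 or 2, WT OXA replicate 4 or KO OXA replicate 4, and 0.0429 with thinned reads): Krt14 rose by 2.04 ± 0.20 (adjusted p = 4.22e-07), Krt15 fell by 2.38 ± 0.28 (adjusted p = 3.11e-06), and Krt5 stood at -0.22 ± 0.22 (adjusted p = 0.477). Reads of close paralogs (Krt6a and Krt6b, the Sprr2 and Lce1 families) may be shared, so single members are uncertain.

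Of 38 cell cycle genes 25 rose and the other 13 did not pass (the same over the list alone; adjusted p = 2.135e-09, and adjusted p = 0.196 with an estimated correlation). Rrm2, a ribonucleotide reductase subunit, was at 327 ± 89.2 under vehicle and at 3948 ± 499.8 under OXA (3.62 ± 0.21, adjusted p = 2.1e-10). Mcm3, a replication helicase subunit, rose by 2.79 ± 0.26 (adjusted p = 1.78e-07) and Mki67 by 1.64 ± 0.33 (adjusted p = 0.000699). Of 31 fibroblast and matrix genes 9 rose and 1 fell (8 and 1 over the list alone; adjusted p = 0.0269, and 0.485 with an estimated correlation). The call on this list was lost without WT vehicle replicate 1 (adjusted p = 0.0622) and without replicate 2 (0.0823). Timp1, an inhibitor of metalloproteinases, rose by 3.45 ± 0.51 (adjusted p = 3.8e-05) and the matrix protein Tnc by 2.41 ± 0.31 (adjusted p = 8.09e-06), while Col1a1 stood at 0.58 ± 0.26 (adjusted p = 0.0861, but 0.00718 with equal library totals, 0.0102 with quantile normalization, 0.0497 with array weights and 0.023 without WT vehicle replicate 3). Of 20 endothelial markers 11 rose and 9 did not pass (12 rose over the list alone; adjusted p = 0.000384, and 0.289 with an estimated correlation). The adhesion molecule Vcam1 rose by 1.90 ± 0.28 (adjusted p = 3.38e-05) and Pecam1 (CD31) by 1.17 ± 0.25 (adjusted p = 0.00118).

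Of the immune lists camera called some higher in WT, and none passed with an estimated correlation. Of 27 interferon response genes 25 rose (25 over the list alone; adjusted p = 4.85e-10, and 0.283 with an estimated correlation), among them the chemokine Cxcl9 by 4.43 ± 0.46 (adjusted p = 6.46e-07) and the immunoproteasome subunit Psmb8 by 2.54 ± 0.30 (adjusted p = 3.73e-06). Of 18 T cell markers 16 rose and 1 fell (the same over the list alone; adjusted p = 6.35e-05, and 0.289 with an estimated correlation). Cd4 rose by 4.76 ± 0.62 (adjusted p = 1.11e-05). Of 24 macrophage and dendritic cell markers 15 rose and 1 fell (16 and 1 over the list alone; adjusted p = 0.000123, and 0.283 with an estimated correlation). Ccr2, a monocyte chemokine receptor, rose by 2.80 ± 0.31 (adjusted p = 1.33e-06). Of 10 B and plasma cell markers 4 rose (4 over the list alone; adjusted p = 0.02405, and 0.485 with an estimated correlation; 0.139 with equal library totals), and Igha, the IgA heavy chain, rose by 6.81 ± 0.94 (adjusted p = 1.93e-05). Reads of immunoglobulin genes may be shared. Of 21 inflammatory chemokines and cytokines 10 rose and 2 fell (the same over the list alone; adjusted p = 0.0134, and 0.274 with an estimated correlation). Il19 rose by 7.36 ± 0.76 (adjusted p = 6.53e-07), and Il18 fell by 2.44 ± 0.25 (adjusted p = 5.56e-07). Of 8 mast cell and basophil markers 3 rose (3 over the list alone; adjusted p = 0.239). Of 7 neutrophil markers 3 rose and 1 fell (3 and 2 over the list alone; adjusted p = 0.742), with a mean of 0.62 and a median of -0.37.

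Eosinophil transcripts were sparse. Of 11 eosinophil markers 4 passed the filter and 3 of these rose (3 over the list alone; adjusted p = 0.0269, and 0.282 with an estimated correlation). The call on this list was lost without WT vehicle replicate 4 (adjusted p = 0.0548), with equal library totals (0.0768) and with quantile normalization (0.0583). Cd300lf, an inhibitory receptor of myeloid cells, rose by 3.90 ± 0.67 (adjusted p = 0.000189), and Ear2, an eosinophil-associated ribonuclease whose reads may be shared with paralogs, rose by 2.39 ± 0.54 (adjusted p = 0.00207). Epx, eosinophil peroxidase, had 0 reads in all 4 groups, which allows up to 0.0322 CPM in WT OXA and up to 0.0981 in WT vehicle. Ccr3, the eotaxin receptor, had 1 read over the 4 WT vehicle libraries, 37 in WT OXA, 0 in KO vehicle (which allows up to 0.0583 CPM) and 7 in KO OXA. Il13 had 3, 28, 1 and 15 reads in the same order, and Il4 had 2, 29, 3 and 12. Of other eosinophil genes Prg2 had 0 (which allows up to 0.0981 CPM), 29, 1 and 2 reads, Siglecf 0, 11, 1 and 4, and Il5ra 1, 31, 11 and 9. These are reads over groups of unequal depth. On the deposited scale Ccr3 was at 4.34 ± 3.25 in WT OXA and at 2.14 ± 2.65 in KO OXA, Il13 at 2.82 ± 2.80 and at 4.53 ± 2.08, and Il4 at 2.92 ± 2.02 and at 2.67 ± 3.4. Prg2 was at 3.26 ± 0.65 and at 0.395 ± 0.79, Siglecf at 1.04 ± 1.5 and at 0.99 ± 1.19, and Il5ra at 3.26 ± 1.24 and at 2.09 ± 2.01. These genes lay under the filter and were not tested.

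Markers on the muscle and airway lists also moved with WT OXA. Whether the airway markers came from the esophagus or from neighbouring tissue was not tested. Of 11 smooth muscle markers 5 fell (5 over the list alone; adjusted p = 0.00418, and 0.402 with an estimated correlation; 0.0583 with quantile normalization), among them Myh11 by -1.24 ± 0.24 (adjusted p = 0.000586). Of 22 skeletal muscle markers 8 fell and 1 rose (the same over the list alone; adjusted p = 0.00406, and 0.494 with an estimated correlation; 0.329 with quantile normalization). Myh4 fell by 2.63 ± 0.33 (adjusted p = 5.92e-06), while the slow troponin Tnnt1 rose by 1.87 ± 0.34 (adjusted p = 0.000268). Of 4 airway markers tested 2 fell (3 over the list alone; adjusted p = 0.00684, and 0.13 with an estimated correlation). Both are known from club cells: Cyp2f2 was at 41264 ± 8658 and then at 848 ± 214 (-5.62 ± 0.22, adjusted p = 1.16e-12), and Scgb1a1 fell by 3.06 ± 0.50 (adjusted p = 0.000106). Of 18 immediate early and stress genes 2 rose and 6 fell (the same over the list alone; adjusted p = 0.0557, but from 0.0329 to 0.0478 without WT vehicle replicate 1 or 2, WT OXA replicate 1 or 4, or KO OXA replicate 2). Of 13 mitochondrially encoded genes 3 fell (3 over the list alone; adjusted p = 0.114, but 0.0402 without WT vehicle replicate 4). Of 5 sex-linked genes 1 rose (1 over the list alone; adjusted p = 0.448). Among 12 adipocyte markers (adjusted p = 0.282) limma called 0, with 1 higher and 1 lower at an unadjusted p under 0.05 and 0 by edgeR and 1 by DESeq2. Among 4 thyroid markers (adjusted p = 0.532) and 7 glandular stomach markers (adjusted p = 0.794) limma, edgeR and DESeq2 called 0, as did an unadjusted p under 0.05. The thyroid score still differed by the exact permutation test, at 2.90 ± 0.55 under vehicle and 3.87 ± 0.35 under OXA (p = 0.0286, adjusted p = 0.0391). Krt4 took 9.68% ± 1.63 of reads in WT vehicle and 3.62% ± 0.758 in WT OXA.

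By the exact permutation test, 19 of the 26 list scores differed in WT with p = 0.0286, the smallest that 70 assignments can give (adjusted p = 0.0391). With fry every list that camera called in WT passed, from adjusted p = 3.574e-08 for airway markers to 0.04659 for skeletal muscle markers. Without a camera call, basal markers (0.004335, lower), hyperproliferative and alarmin keratinocyte genes (0.01696, higher) and immediate early and stress genes (0.04833, lower) also passed with fry. The number of genes called in WT depended on the scaling between libraries. With equal library totals the median log2 fold change of all genes moved by 0.31, and 5121 genes rose and 1495 fell, so that 77.4% of calls were increases against 53.0% with the deposited scaling.

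The second comparison asked which part of the OXA response was seen without Il13ra1. In KO mice 303 genes rose and 15 fell (1.90%). The monocyte chemokine Ccl8 was at 26.3 ± 4.24 under vehicle and at 1286 ± 614 under OXA, a log2 fold change of 5.42 ± 0.37 (adjusted p = 7.38e-08). Cxcl9 was at 7.93 ± 2.06 and then at 449 ± 260.4 (5.38 ± 0.46, adjusted p = 2.16e-06), and Gzmb, granzyme B of cytotoxic lymphocytes, rose by 6.26 ± 0.87 (adjusted p = 0.000228). Of 27 interferon response genes 24 rose (25 over the list alone; adjusted p = 7.36e-51, and adjusted p = 0.0075 with an estimated correlation). Gbp2, an interferon-induced GTPase, rose by 3.45 ± 0.32 (adjusted p = 5.21e-06) and Psmb8 by 3.34 ± 0.30 (adjusted p = 3.94e-06).

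Of 24 macrophage and dendritic cell markers 11 rose in KO (19 over the list alone; adjusted p = 1.43e-24, and 0.0075 with an estimated correlation). The antigen-presenting genes H2-Ab1 and Cd74 rose by 2.2 ± 0.25 (adjusted p = 3.45e-05) and 1.89 ± 0.24 (adjusted p = 9.23e-05), and the complement gene C1qb by 1.90 ± 0.24 (adjusted p = 9.23e-05). Of 21 inflammatory chemokines and cytokines 6 rose (7 over the list alone; adjusted p = 2.28e-08, and 0.0075 with an estimated correlation), with Ccl12 at 4.73 ± 0.51 (adjusted p = 1.9e-05). Of 23 IL-4 and IL-13 response genes 6 rose (8 over the list alone; adjusted p = 6.4e-09, and 0.0075 with an estimated correlation): Retnla rose by 1.76 ± 0.25 (adjusted p = 0.000236) and Mrc1, the macrophage mannose receptor, by 1.14 ± 0.21 (adjusted p = 0.00319). Ccl8, given above, is a member of this list and was another of the 6. Chil4 stood at 1.46 ± 0.72 (adjusted p = 0.371) and Ccl11 at 0.52 ± 0.20 (adjusted p = 0.248). Of 18 T cell markers 2 rose (7 over the list alone; adjusted p = 1.41e-07, and 0.211 with an estimated correlation). Of 20 hyperproliferative and alarmin keratinocyte genes 3 rose (10 over the list alone; adjusted p = 3.665e-09, and 0.133 with an estimated correlation). Krt6b rose by 3.27 ± 0.61 (adjusted p = 0.00392) and Krt6a by 2.27 ± 0.46 (adjusted p = 0.00864), the latter lost without KO OXA replicate 2 (adjusted p = 0.0505).

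Few members of the epithelial and stromal lists passed in KO. Of 38 cell cycle genes 1 fell (3 rose and 1 fell over the list alone; adjusted p = 0.963), with a mean of 0.01 and a median of -0.05, and Mki67 stood at -0.58 ± 0.33 (adjusted p = 0.443). Of 20 endothelial markers 1 fell (2 rose and 4 fell over the list alone; adjusted p = 0.0116, and 0.4365 with an estimated correlation), a call lost without KO vehicle replicate 3 (adjusted p = 0.0613), KO OXA replicate 2 (0.0762) and KO OXA replicate 3 (0.0573). Of 31 fibroblast and matrix genes 1 rose (adjusted p = 0.543, but 0.0367 and lower, with a mean of -0.07, without KO vehicle replicate 4), with a mean of 0.05 and a median of -0.0032. In 6 lists camera called a shift although limma called 0 members. Among them were suprabasal genes, higher (adjusted p = 0.0289, and 0.626 with an estimated correlation; 4 higher at an unadjusted p under 0.05, and 2 by DESeq2 and 0 by edgeR), and smooth muscle (0.00191), skeletal muscle (0.000211) and adipocyte markers (0.00278), lower. With an estimated correlation the muscle and adipocyte lists were at adjusted p = 0.4, 0.4365 and 0.4. In them 2, 4 and 2 members were lower at an unadjusted p under 0.05, and edgeR and DESeq2 called 0. The suprabasal call was lost without KO vehicle replicate 1 (0.0915) or 3 (0.0521) without KO OXA replicate 1 (0.162) or 3 (0.179), with equal library totals (mean 0.12, 0.0658) and with quantile normalization (mean 0.09, 0.421), against a mean of 0.24. The adipocyte call was lost without KO OXA replicate 4 (0.0506). Receptor components (adjusted p = 0.00714, and 0.0479 with an estimated correlation) and mast cell and basophil markers (0.0214, and 0.4 with an estimated correlation) were the others, higher by camera. Of their members 3 and 2 were higher at an unadjusted p under 0.05, limma called 0, edgeR 0 and 2, and DESeq2 1 and 1. The mast cell call was lost without KO vehicle replicate 1 (0.0915) and KO OXA replicate 2 (0.208). Krt14 stood at 0.62 ± 0.20 (adjusted p = 0.148, but 0.0335 with DESeq2), Flg at 1.42 ± 0.47 (adjusted p = 0.156, but 0.0401 with DESeq2) and Cyp2f2 at -0.34 ± 0.22 (adjusted p = 0.52). The other lists did not pass in KO (adjusted p from 0.141 for eosinophil markers to 0.619 for thyroid markers), although eosinophil markers passed, higher, with thinned reads (mean 1.35, 0.0456). Without KO OXA replicate 2, B and plasma cell markers, with a mean of -0.39 and a median of 0.11, were called lower (0.0291) and immediate early and stress genes higher (0.00685), and without KO OXA replicate 3 mitochondrially encoded genes were called lower (0.00676).

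By the exact permutation test, 7 of the 26 list scores differed in KO with p = 0.0286, interferon, macrophage and response scores among them, but none passed (adjusted p = 0.106). With only 7 lists at the smallest possible p, none could pass the adjustment. With fry T cell markers (adjusted p = 0.04945) and hyperproliferative and alarmin keratinocyte genes (0.02264) passed in KO. Suprabasal, endothelial, muscle, adipocyte and mast cell lists did not pass with fry (from 0.1707 to 0.3469). The KO count rested on single libraries. It was 875 rose and 157 fell without KO OXA replicate 4, 174 and 8 without KO OXA replicate 2, 188 and 5 without KO OXA replicate 1, 193 and 2 without KO vehicle replicate 3, and 200 and 4 without KO vehicle replicate 1. The number that fell was also 28 without WT vehicle replicate 4, 9 without KO vehicle replicate 4, 8 without WT OXA replicate 2, and 7 without WT OXA replicate 3 or KO vehicle replicate 2.

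The interaction tested whether the OXA effect differed between genotypes. It was more positive in KO for 1698 genes and more negative for 1284 (17.8%). Flg, which fell in WT, had a KO effect more positive by 7.80 ± 0.66 (adjusted p = 1.54e-07) and stood at 573 ± 206 in KO OXA. For Chil4 the KO effect was more negative by -5.95 ± 1.02 (adjusted p = 0.000562), for Krt6a by -4.36 ± 0.65 (adjusted p = 0.000138) and for Rrm2 by -3.33 ± 0.29 (adjusted p = 2.25e-07). For Ccl8 it was more positive by 2.60 ± 0.52 (adjusted p = 0.00195). Ccl8 started lower in KO: vehicle values ran from 55.7 to 199.7 in WT and from 20.5 to 29.5 in KO. Under OXA they ran from 521 to 934 in WT and from 548 to 1806 in KO, and so overlapped.

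**Figure D3:**
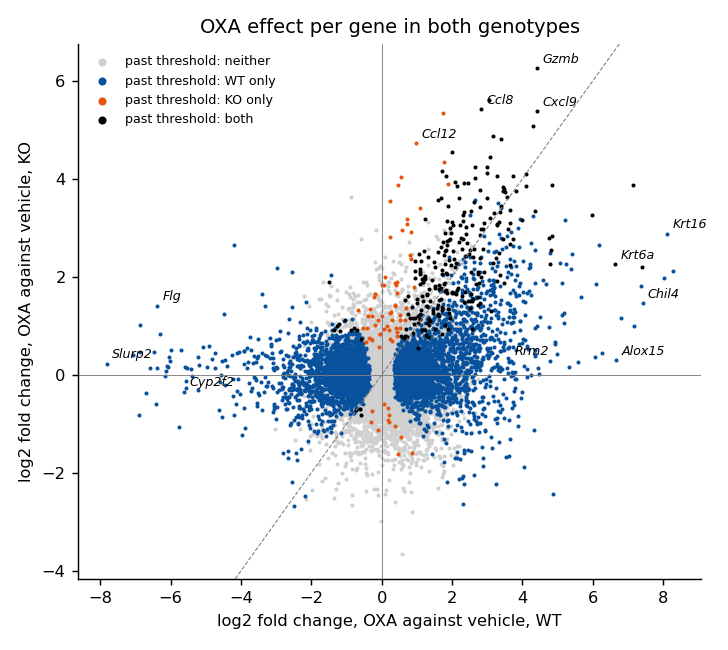
Each gene's log2 fold change under OXA in WT (horizontal axis) against that in KO (vertical axis), coloured by which comparisons called it, with a dashed line of equal effects. Across genes r was 0.261. The genes called in WT, which were picked by their WT change, had a median KO change of 0.12 where they rose and -0.0052 where they fell.

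Across all tested genes the WT and KO effects had a Pearson r of 0.261 (jackknife SE 0.144, from 0.178 to 0.321 with single libraries left out) and a Spearman rho of 0.114. Genes are not independent replicates, so no p is given. Genes that rose in WT had a median log2 fold change of 1.16 there and 0.12 in KO, and genes that fell had -0.96 in WT and -0.0052 in KO. These genes were picked by their WT change, which by itself can enlarge the WT medians against the KO ones. By the interaction test, 2640 of the 5692 WT calls (46.4%) had an interaction that opposed the WT change. Of the 303 genes that rose in KO, 76.9% also rose in WT: 233 rose in both, against 54.6 for independent lists. Another 3 fell in both, against 2.39 for independent lists, and 10 were called in opposite directions. The 2 effects shared 1 spread per gene, so the lists were not independent and these expected numbers are only rough.

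Of 38 cell cycle genes, 18 had a more negative effect in KO and the other 20 did not pass (21 over the list alone; adjusted p = 3.727e-09, and adjusted p = 0.483 with an estimated correlation). Mcm3 was at -2.24 ± 0.37 (adjusted p = 0.000399) and Mki67 at -2.23 ± 0.46 (adjusted p = 0.00261). Of 31 suprabasal genes 14 were more positive and 4 more negative (17 and 4 over the list alone; adjusted p = 1.627e-05, and 0.5435 with an estimated correlation). Hrnr was at 5.38 ± 0.58 (adjusted p = 3.61e-06) and Ppl, periplakin, at 2.13 ± 0.24 (adjusted p = 5.03e-06). Slurp2 was at 8.05 ± 0.67 (adjusted p = 9.99e-08). Of 20 endothelial markers 9 were more negative (15 over the list alone; adjusted p = 1.627e-05, and 0.527 with an estimated correlation), with Pecam1 at -1.69 ± 0.35 (adjusted p = 0.00256). Of 13 basal markers 4 were more positive and 1 more negative (4 and 2 over the list alone; adjusted p = 0.274), with Krt15 at 2.73 ± 0.40 (adjusted p = 0.000109) and Krt14 at -1.42 ± 0.29 (adjusted p = 0.00234). Of 23 IL-4 and IL-13 response genes 1 was more positive and 4 more negative (1 and 5 over the list alone; adjusted p = 0.351), with Alox15 at -6.36 ± 1.42 (adjusted p = 0.00449). Of 8 receptor components 1 was more positive and 2 more negative (1 and 4 over the list alone; adjusted p = 0.351). With fry the receptor list passed, more negative in KO (adjusted p = 0.007101). Il4ra was at -1.93 ± 0.34 (adjusted p = 0.000676), while Il13ra1 itself did not pass (-1.09 ± 0.46, adjusted p = 0.107), except with equal library totals (0.0345) and without KO OXA replicate 2 (0.0198).

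**Figure D4:**
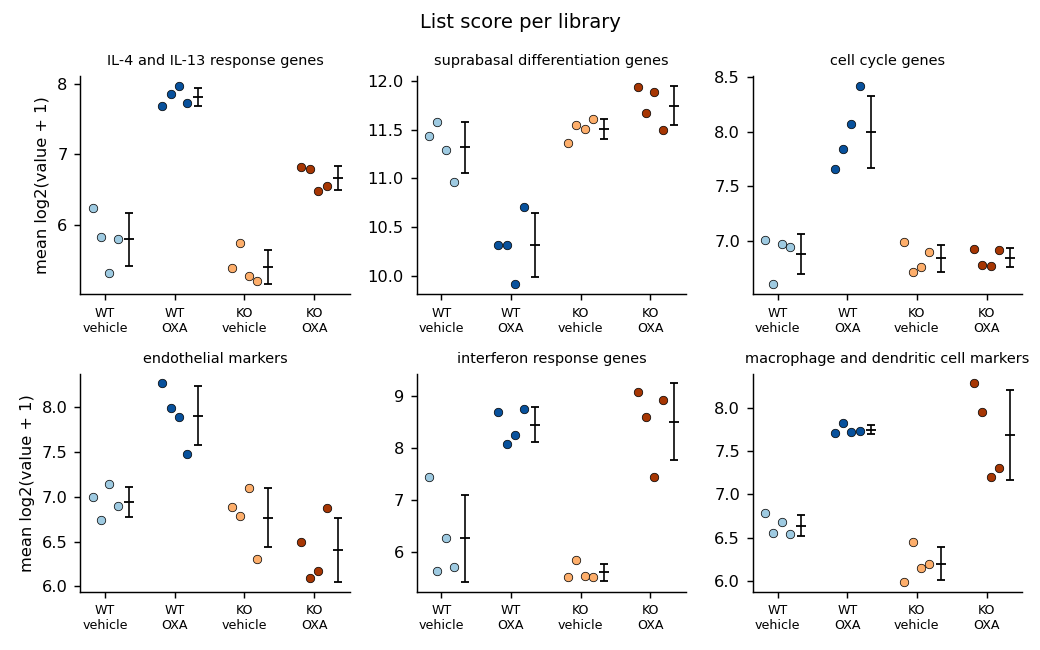
Scores of 6 gene lists per library, as mean log2(value + 1) of the tested members, by group; points are libraries and bars are means ± SD (n = 4). Cell cycle and endothelial scores were higher in WT OXA than in WT vehicle, while interferon scores were higher under OXA in both genotypes.

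Of 27 interferon response genes, 4 had a more positive effect in KO (3 over the list alone; adjusted p = 0.01871, and unadjusted p = 0.425 with an estimated correlation). The call was lost without WT vehicle replicate 1 (adjusted p = 0.158), KO OXA replicate 1 (0.0577) and KO OXA replicate 4 (0.095). The interferon score of KO differed from that of WT by -0.66 under vehicle and by 0.06 under OXA. The interaction of this list thus came mostly from the vehicle groups. Irf9, a subunit of the interferon-activated transcription factor, was at 1.84 ± 0.28 (adjusted p = 0.000207). Of 24 macrophage and dendritic cell markers 5 were more positive and 2 more negative (the same over the list alone; adjusted p = 0.165, but 0.037 without KO OXA replicate 3), with C1qb at 1.45 ± 0.34 (adjusted p = 0.00642). Of 10 B and plasma cell markers 3 were more negative (3 over the list alone; adjusted p = 0.0196, and 0.66 with an estimated correlation), with Igha at -5.65 ± 1.33 (adjusted p = 0.00608). That call was lost without KO vehicle replicate 2 (0.0965) or KO OXA replicate 4 (0.095) and with equal library totals (0.198). Of 31 fibroblast and matrix genes 7 were more negative (7 over the list alone; adjusted p = 0.02677, and 0.66 with an estimated correlation). That call was lost without WT vehicle replicate 1 (0.0745) or 2 (0.0781), KO vehicle replicate 1 (0.069), and KO OXA replicate 2 (0.0712) or 4 (0.1). Eln, elastin, was at -2.03 ± 0.37 (adjusted p = 0.000961). Of 4 airway markers 2 were more positive (2 over the list alone; adjusted p = 0.0196, and 0.358 with an estimated correlation; 0.068 without KO OXA replicate 4), with Cyp2f2 at 5.27 ± 0.32 (adjusted p = 1.43e-09). Of 18 immediate early and stress genes 5 were more positive and 2 more negative (6 and 2 over the list alone; adjusted p = 0.03433, and 0.66 with an estimated correlation). That call was lost without WT vehicle replicate 4 (0.0889), WT OXA replicate 2 (0.0643) or KO OXA replicate 4 (0.149). It was also lost with equal library totals (mean 0.08 against 0.52, 0.122), with quantile normalization (0.14) and with the stricter filter (0.0716). The heat shock gene Dnajb1 was at 1.48 ± 0.27 (adjusted p = 0.000834). Of 20 hyperproliferative and alarmin keratinocyte genes 6 were more positive and 5 more negative (the same over the list alone; adjusted p = 0.794), with a mean of -0.28 and a median of 0.10. The direction of the counts depended on the scaling: with equal library totals the median moved by -0.43, and 884 genes were more positive and 3467 more negative.

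The comparison of genotypes under vehicle asked what the loss of Il13ra1 does without the model. In KO 6 genes were higher and 4 lower. Cyp2ab1 was higher by 3.71 ± 0.51 (adjusted p = 0.00284, and 0.0948 with only the compared groups). It passed in all 16 fits without 1 library. Rnf167, Dynlt1a and Cd59a were higher by 1.20 ± 0.22 (adjusted p = 0.0443), 1.08 ± 0.18 (0.0266) and 1.06 ± 0.19 (0.0416). Acsm3, Hspa1a and Gm15446 were at -4.01 ± 0.72 (0.0416), -1.57 ± 0.29 (0.0497) and -3.23 ± 0.55 (0.0267), the last chosen after its values were seen. Each of these 6 genes lost its call in 7 to 12 of the 16 fits without 1 library (adjusted p from 0.0502 to 0.198). All 6 also lost it without trend (0.0512 to 0.181), all but Dynlt1a without a filter (0.0887 to 0.142), and all but Rnf167 with thinned reads (0.0502 to 0.163). Dynlt1a, Cd59a and Gm15446 lost it with only the compared groups (0.211, 0.156 and 0.274), and Cd59a, Acsm3 and Hspa1a with edgeR (0.0754, 0.121 and 0.0604). Rnf167, Dynlt1a, Acsm3 and Hspa1a lost it with equal library totals (0.0608 to 0.0694), and Rnf167, Acsm3 and Hspa1a with a pseudocount of 0.5 (0.0512 to 0.054). Il4ra stood at -0.06 ± 0.24 (adjusted p = 0.96).

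Under vehicle, camera called interferon response genes (adjusted p = 5.524e-09), macrophage and dendritic cell markers (3.448e-06), immediate early and stress genes (6.173e-06), fibroblast and matrix genes (0.000125), IL-4 and IL-13 response genes (0.0113) and receptor components (0.0448) lower in KO, and mitochondrially encoded genes higher (0.0406). With an estimated correlation none passed (adjusted p = 0.384, 0.321, 0.245, 0.337, 0.245, 0.245 and 0.766 in that order). The call on response genes was also lost without WT vehicle replicate 1 (0.0952). That on receptor components was lost without WT vehicle replicate 1, 3 or 4, KO vehicle replicate 1 or 4, or KO OXA replicate 3 (0.0509 to 0.131) and with the stricter filter (0.0617), and that on mitochondrially encoded genes without WT vehicle replicate 2 or 4 or KO vehicle replicate 4 (0.113 to 0.241). The receptor list of 8 tested genes holds the knocked-out Il13ra1 itself, the only 1 called lower (-1.93, against a list mean of -0.39). Part of its shift was thus fixed by the genotype. By the exact permutation test 2 of the 26 list scores had p = 0.0286 under vehicle, and none passed (adjusted p = 0.371). With only 2 lists at this smallest possible p, none could pass the adjustment. Over the list alone 7 of 27 interferon genes, 4 of 24 macrophage and dendritic cell markers and 4 of 18 immediate early genes were lower. The interferon score was 7.45 in WT vehicle replicate 1, and 5.63, 6.26 and 5.71 in replicates 2, 3 and 4. In KO vehicle it ran from 5.51 to 5.84, so much of the difference rested on WT vehicle replicate 1. Cxcl9 stood at -1.72 ± 0.46 (adjusted p = 0.289, but 0.041 with DESeq2) and H2-Ab1 at -1.11 ± 0.25 (adjusted p = 0.206, but 0.00608 with DESeq2 and 0.0388 without WT vehicle replicate 2). The 10 calls changed with single libraries. There were 3 higher and 0 lower without WT vehicle replicate 3, WT OXA replicate 2 or KO vehicle replicate 1, with 1529 genes at an unadjusted p under 0.05 in all 16 libraries, where edgeR called 5 and 2 and DESeq2 20 and 23. There were 3 and 1 without KO vehicle replicate 2, 3 or 4, 4 and 1 without WT OXA replicate 1, 5 and 0 without WT vehicle replicate 1, and 9 and 3 without WT vehicle replicate 2.

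The comparison of genotypes under OXA asked how the treated mice differed. In KO 2450 genes were higher and 2167 lower than in WT (27.6%). Flg was higher by 7.83 ± 0.47 (adjusted p = 2.53e-10), Slurp2 by 8.35 ± 0.47 (adjusted p = 1.14e-10) and Il18 by 3.27 ± 0.25 (adjusted p = 8.84e-09). Chil4 was at -7.28 ± 0.72 (adjusted p = 3.93e-07), Alox15 at -7.18 ± 1.0 (adjusted p = 2.59e-05), Krt17 at -3.99 ± 0.44 (adjusted p = 1.48e-06) and Il13ra2 at -3.34 ± 0.81 (adjusted p = 0.0042). Retnla stood at -0.15 ± 0.25 (adjusted p = 0.693), although with quantile normalization it passed (0.0344).

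Of 38 cell cycle genes 27 were lower in KO (29 over the list alone; adjusted p = 6.551e-13), of 20 endothelial markers 16 (17 over the list alone; 2.679e-08) and of 31 fibroblast and matrix genes 15 (19 over the list alone, where 1 was higher; 5.362e-06). Of 31 suprabasal genes 19 were higher and 4 lower (21 and 5 over the list alone; adjusted p = 4.086e-07). None of these lists passed with an estimated correlation (adjusted p = 0.2185 for each of the 4). By the exact permutation test 11 of the 26 list scores had p = 0.0286, and none passed (adjusted p = 0.0675). With only 11 lists at this smallest possible p, none could pass the adjustment. Rrm2 was at -3.16 ± 0.21 (adjusted p = 8.91e-10), Kdr, a VEGF receptor, at -2.14 ± 0.32 (adjusted p = 5.59e-05), Mmp14 at -1.66 ± 0.20 (adjusted p = 5.23e-06) and Col1a1 at -1.38 ± 0.26 (adjusted p = 0.000464). Of 23 IL-4 and IL-13 response genes 1 was higher and 8 lower (4 and 8 over the list alone; adjusted p = 0.0514, and 0.2185 with an estimated correlation). That list passed, lower in KO, without any one of 10 libraries (WT vehicle 1, 2 and 3, WT OXA 1 and 4, KO vehicle 2 and 3, KO OXA 1, 2 and 3; adjusted p from 0.0214 to 0.0474), and with a pseudocount of 5 (0.0173), quantile normalization (0.022) and thinned reads (0.0362). Of 27 interferon response genes 2 were higher and 1 lower (2 higher over the list alone; adjusted p = 0.779), with a mean of 0.06 and a median of -0.13. Irf9 was higher by 1.40 ± 0.20 (adjusted p = 3.47e-05). Of 24 macrophage and dendritic cell markers 3 were higher and 2 lower (the same over the list alone; adjusted p = 0.779), with Cd207, langerin of Langerhans cells, higher by 3.69 ± 0.70 (adjusted p = 0.000542). With equal library totals the median moved by -0.40, and 1271 genes were higher and 5117 lower.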

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

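The tests in this part were chosen after the results were seen, except the depth test of KO OXA replicate 4, whose bound was set before its value was seen.

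OXA changed 5692 genes in WT, whose OXA libraries were the deepest. Deeper sequencing could add calls, but with every library thinned to equal depth 87.37% of the calls were kept with the same direction, which argues against depth as the whole source. A lower share of muscle in the samples could raise all epithelial genes alike, but of the called genes of the 3 epithelial lists 26 fell and 17 rose, so that 60.47% fell, which argues against it for the epithelial changes. By limma, 1 of the 35 splits of the 8 libraries into 4 and 4, the real one, gave as many genes (5692 against a highest other of 0). This is the lowest share that 35 splits can give, so they argue against chance but cannot exclude it. A response of the tissue to OXA is left as a hypothesis, since it was weighed on the same data. Depth and the share of mitochondrial rRNA also moved with this group, and the labels gave no batch. A difference in the handling of the WT OXA libraries therefore cannot be told apart from the treatment by these tests. The interaction and KO against WT under OXA use the same libraries.

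KO OXA replicate 4 had reads in 23730 genes, the most of the 16 libraries, and 1477 of them had no read in any other library, against at most 335 such genes in another library. Depth was argued against: at equal depth it still had 21771 genes, 13.95% above the 19105 of the next library. Genomic DNA could give reads over genes that are otherwise silent, and would put the X chromosome at about 0.5 of the autosomes with 1 X copy. Over genes with no read in the other 15 libraries the ratio was 0.7187 (95% bootstrap interval 0.473 to 1), so genomic DNA and a wider range of transcripts cannot be told apart, because the interval holds 0.5 and reaches 1. A biological source in this sample was not tested.

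In KO, 2 of the 35 splits gave as many genes as the real split (318), and the highest other gave 509, so chance cannot be excluded for this count. That split exchanged KO vehicle replicate 4 with KO OXA replicate 4, which had Cxcl9 at 8.21 and 390.0. Without KO OXA replicate 4, 1 of 35 splits of the other 7 libraries, the real one, gave as many (1032, highest other 138). This was the library exchanged above, it was picked after its left-out count was seen, and that count was the highest of the 16 left-out fits. Splits without another library were not tested, so the KO count stays open to chance. For KO against WT, 1 of 35 splits gave as many under vehicle (10, highest other 2) and 1 of 35 under OXA (4617, highest other 239), the real one in both. Since 1 of 35 is the lowest share possible, chance cannot be excluded by these splits. The 10 calls under vehicle also changed with single libraries. For the interaction 1 of 100 splits, the real one, gave as many (2982). The highest other gave 2316, and it kept the real division of the OXA libraries.

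The OXA effect differed between genotypes by the interaction test for 1698 genes that were more positive and 1284 that were more negative in KO. By camera's adjusted p it differed for cell cycle genes (3.727e-09), suprabasal differentiation genes (1.627e-05), endothelial markers (1.627e-05), interferon response genes (0.01871), airway markers (0.0196), B and plasma cell markers (0.0196), fibroblast and matrix genes (0.02677), and immediate early and stress genes (0.03433). With an estimated correlation all 8 calls were lost (adjusted p from 0.3578 to 0.8288). With fry, airway markers (adjusted p = 4.127e-06), cell cycle genes (0.002133), suprabasal genes (0.005651) and endothelial markers (0.007101) passed. Immediate early and stress genes (0.07815), fibroblast and matrix genes (0.09196), B and plasma cell markers (0.1282) and interferon response genes (0.3464) did not pass with fry. Of the lists that camera did not call, receptor components (0.007101) and type 2 cytokines and alarmins (0.01395) passed with fry, more negative in KO.

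In 9 of 128 groups of 4 libraries 1 library stood far from the other 3, where chance gives about 6.4. KO vehicle replicate 2 had a score of B and plasma cell markers of 7.4746 (others 2.6735 to 3.3801), of interferon response genes of 5.8449 (others 5.514 to 5.5377) and a Krt4 share of reads of 8.2648% (others 9.9559% to 10.265%). KO vehicle replicate 3 had a mitochondrial share of 10.051% (others 11.287% to 11.494%) and an immediate early and stress score of 8.4921 (others 8.5782 to 8.5956). KO vehicle replicate 4 had an adipocyte score of 5.8532 (others 7.1408 to 7.3584). KO OXA replicate 1 had a fibroblast and matrix score of 8.8172 (others 8.5365 to 8.5681), and KO OXA replicate 4 a receptor component score of 7.233 (others 6.7692 to 6.8135). WT vehicle replicate 2 had a cell cycle score of 6.6041 (others 6.9463 to 7.0061).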

How the results depend on the processing

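Thinning to equal depth was the alternative chosen after seeing the data. Of the calls of KO against WT under OXA 28 changed sign with equal library totals and 4 with quantile normalization, and of the WT calls 2 with quantile normalization. No named gene changed its call with the opposite sign. Of the lists, fibroblast and matrix genes in the KO effect did: the mean was 0.05 without a call, and -0.07 and called lower (adjusted p = 0.0367) without KO vehicle replicate 4. Of the values of named genes, with the left-out fits entered only as their lowest and highest, 1728 kept their call, 46 lost it and 14 gained it. Of the values of lists, counted likewise, 1147 kept theirs, 86 lost it and 52 gained it, of which estimated correlation took 43, and fry took 17 and gave 10. The counts that moved by over 1.5 times follow. The cause was not tested unless stated. With equal library totals WT counts were 5121 higher and 1495 lower, the interaction 884 and 3467, KO against WT under OXA 1271 and 5117, and under vehicle 1 lower. The balance of the interaction (1698 and 1284) and of KO against WT under OXA (2450 and 2167) was reversed by this. In the KO effect the number higher was 194 with only the compared groups and 652 with DESeq2. The number lower was 8 without a filter, 29 with quantile normalization, 5 with only the compared groups, 26 with array weights and 69 with DESeq2. Under vehicle the number higher was 3 with only the compared groups, 3 without trend and 20 with DESeq2. The number lower was 2 with a pseudocount of 0.5, 0 without a filter, 0 without trend, 2 with edgeR, 23 with DESeq2 and 1 with thinned reads; 1529 genes had an unadjusted p under 0.05 in limma. With single libraries left out the KO effect ranged from 174 to 875 higher and from 2 to 157 lower, and the vehicle comparison from 3 to 9 higher and from 0 to 5 lower. The WT, interaction and OXA counts stayed within 1.5 times under every alternative but equal library totals. Genes with few reads were not tested: Epx had 0 reads, and Il13, Il4 and Ccr3 fell under the filter. Whether depth was the reason was not tested.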

Other observations

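Gene families were looked at after their values were seen. All 8 Sprr2 genes, small proline-rich proteins of the cornified envelope, rose in WT under OXA (median log2 fold change 6.62), and 7 of the 8 had a more negative effect in KO (median -4.70). All 14 Lce1 genes, late cornified envelope proteins from the same chromosomal complex, fell in WT (median -5.64) and all 14 had a more positive effect in KO (median 5.98). The same counts held with equal library totals and with quantile normalization, though reads may be shared within both families. Of 21 glutathione S-transferase genes (Gst), detoxification enzymes, 13 fell and 1 rose in WT (median -1.06), and 12 had a more positive effect in KO (median 1.38). With equal library totals 12 fell and 1 rose, and with quantile normalization 13 fell and 1 rose. Of 74 ribosomal protein genes 51 fell in WT (median -0.80) and 58 had a more positive effect in KO (median 1.38). With equal library totals 35 fell and 2 rose, and with quantile normalization 39 fell and 4 rose. In each group the deepest library had the lowest share of ribosomal protein reads (WT vehicle 5.22%, WT OXA 3.89%, KO vehicle 4.41%, KO OXA 4.73%). WT OXA was also the deepest group, and whether depth or handling of the libraries moved these genes was not tested.

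Members of several immune gene families rose with OXA. All 6 Gbp genes, guanylate-binding proteins, rose in WT (median 1.94) and in KO (median 2.69), though 5 rose in KO with equal library totals, and 2 had a more positive effect in KO (1 with equal library totals). Of 8 Oas genes, sensors of double-stranded RNA, 7 rose in WT (median 2.32) and 6 in KO (median 2.82), 5 with equal library totals. Of 7 Slfn genes, schlafen proteins, 7 rose in WT (median 3.45) and 3 in KO (median 2.77, lowest -0.93), 4 with quantile normalization, and 1 had a more negative effect in KO (2 with equal library totals). All 3 C1q genes, which macrophages express, rose in KO (median 1.62), and 1 rose in WT (median 0.45), where 3 rose with equal library totals or quantile normalization; 2 had a more positive effect in KO (1 with either scaling). Of 15 Klr genes, lectin-like receptors of natural killer cells, 10 rose in WT (median 2.67; 9 with quantile normalization) and 5 in KO (median 1.32), and limma called no interaction among them (equal library totals called 1).

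Between genotypes 16 genes were above and 19 below in all 8 KO against all 8 WT libraries, where chance separates 0.0155% of genes. Of the genes called under vehicle and under OXA, 7 were called in the same direction in both comparisons (taken up after their values were seen). Among them Cd59a, Dynlt1a and Rnf167 were higher in KO, and Gm15446 and Il13ra1 lower.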
